A study of Mus musculus with 5 samples.

How the data were processed

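The data were 5 mouse gene arrays of whole liver tissue, 2 from control livers and 3 from Hdac3-null liver tumours, of mice about 10 months old. RNA was labelled by a whole-transcript sense method, per the labels. The deposited table holds 1 log2 expression value per probe set and array. GCOS and RMA are named for it in the submitters' processing notes, with no version or role. RMA corrects the background, normalises arrays by quantiles and summarises probes on the log2 scale, which compresses large and low differences. The genome build and the probe set annotation behind the table are not given in the sources used here, apart from the probe table described next. Samples were grouped by the genotype and tissue in their labels, and 0 columns of other samples were present.

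Probe sets were named through the gene symbols of a probe table from the platform's annotation. Of 28853 probe sets, 21789 had 1 symbol, 1621 had several and 5443 had none; the last 2 kinds were left out of the main test. Entrez identifiers of 21698 probe sets were found in a gene table of assembly GRCm38.p6, and 0 symbols needed an update. For 999 genes with more than 1 probe set, the probe set with the highest mean over all 5 arrays was used, which left 19938 genes, with no filter on dim genes.

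Tumour minus control differences were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with all 5 arrays, no covariate, 3 residual degrees of freedom and an estimated 2.98 prior degrees of freedom. P-values are two-sided and were adjusted by Benjamini-Hochberg, and 0.05 was the threshold. Intervals are 95% confidence intervals of that fit. Changes of at least 2-fold had an absolute log2 change of at least 1. No batch or scan date is given in the labels used here.

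The 40 gene lists, with 1100 entries of which 995 were measured, were fixed before the data were examined, as were the tests and the alternatives unless stated otherwise. Some genes stand in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 40 lists: 26 were called, 16 up and 10 down. Camera with an estimated correlation called 0 lists (lowest adjusted p = 0.192), and fry, which asks whether the members move one way on balance, called 11. With an estimated correlation, camera also rests on the 3 residual degrees of freedom, so it can lose a list whose members vary independently. The male-biased list went from camera adjusted p = 2.4e-14 to 0.192 at an estimated correlation of 0.0165, close to the preset one. Calls lost there are therefore no measure of correlation between members. The lists called by fry were all among those called by camera. They were the male-biased, NRF2, cholangiocyte, macrophage, fetal and cancer marker, sterol, glycolysis, clock, bile acid, NF-kB and P450 lists. The other lists called by camera did not pass fry. Members of a list were also tested with adjustment over the list alone.

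Genes were named by a rule fixed beforehand. It takes Hdac3, the 15 largest rises and 15 largest falls among called genes whose tumour values all lie beyond both controls, up to 4 members of each list with the smallest p and all measured members of the corepressor complex. It adds the 10 genes with the largest range among the tumours, and skips gene models without a proper name. Alb, Afp, Saa4, Crp and Cd163 lie outside the rule and were chosen after their values were seen.

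The procedure was tested on simulated arrays, in which 200 of 19938 genes were changed per run. Each gene had limma's spread estimate from the real arrays, the same in both groups, and genes varied independently. It recovered 1.41% of genes changed by 0.5 log2 units, 52.4% of those changed by 1 and 96.2% of those changed by 2, and 7.17% of its calls were unchanged genes. The list test called the shifted list in 10 of 10 runs and 0 unshifted lists. Since simulated genes varied independently, this does not cover lists whose members vary together, such as the mitosis list (estimated correlation 0.61).

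The alternatives were quantile normalisation repeated on the deposited values, a shift of each array to a common median, removal of the dimmest 40% of genes, the mean of all probe sets of a gene, all probe sets as separate features, a variance trend with robust settings, array weights, a replicate block, an ordinary test per gene without moderation, other thresholds, treat against a 1.2-fold change, other list tests and leaving out each array in turn. Where a control was left out, the lone control was assumed to vary like the tumours. Python 3.11.15 with pandas 2.3.3 joined the tables and matplotlib 3.10.9 drew the figures. For runs of neighbouring genes, genes with a mean log2 value of at least 6 were ordered as in GRCm38.p6, and medians were taken over windows of 51 genes, or of 25 where every other gene was held out.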

Results

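Transcript levels were measured on 5 Affymetrix gene arrays, each hybridised with RNA from the liver of a male mouse about 10 months old. The 2 control livers were normal tissue from mice with a floxed and a wild-type Hdac3 allele. These mice carried Cre recombinase under the albumin promoter, which acts in hepatocytes. Cre acts on that floxed allele too, so control hepatocytes keep only the wild-type allele and are not at full Hdac3 dosage. The 3 other samples were liver tumours from mice in which the floxed allele was paired with a null allele, so that Cre leaves their hepatocytes without Hdac3, a histone deacetylase. The labels call the arrays of a group biological replicates. Array medians lay between 5.66 and 5.77 on the deposited log2 scale, and the number of arrays limited the precision. Every null sample was tumour tissue and every control was normal tissue, so the comparison joins genotype and tumour.

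Hdac3 itself was lower in all 3 tumours than in both control livers. Its log2 values were 8.21 and 8.37 in the controls and 6.78, 6.57 and 6.65 in tumours 1, 2 and 3, a log2 change of −1.62 (95% confidence interval −1.95 to −1.30, n = 2 and 3; limma adjusted p = 0.00298). The position of the probes relative to the deleted part of the gene was not analysed here. A probe outside that part does not measure the deletion directly. Of the 4 measured members of the corepressor complex through which Hdac3 acts, Tbl1x rose by 0.99 and Tbl1xr1 by 0.91, Hdac3 fell, and Gps2 did not pass the test (0.06, a sign that turned when arrays were shifted to a common median). The complex as a list was not shifted against other genes (camera adjusted p = 0.408), and with adjustment over the list alone the same numbers resulted, 2 risen and 1 fallen. The calls for Hdac3, Tbl1x and Tbl1xr1 were all lost when control 1 or control 2 was left out, with Hdac3 at adjusted p = 0.0505 and 0.0663.

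Slc7a11, the cystine transporter, had the largest measured rise, 6.53 log2 units (SE 0.40), from control values of 3.45 and 4.34, whose mean lies under the lower quartile of the control arrays. Elovl7, a fatty acid elongase, rose by 5.96, Igfbp1 by 5.69, the iron-binding protein gene Lcn2 by 5.47 and Ly6d by 5.39. Among the 15 largest rises were also Apela, Cldn6, Scd2, Casp12, Cpe, Fabp4, Mmp12, Slc34a2, Sprr1a and Gipc2, the last at 4.43. The sulfotransferase Sult2a8 had the largest measured fall, −7.53 (SE 0.43), from log2 values of 11.60 and 11.72 in the controls to 3.30, 4.86 and 4.25 in the tumours. Serpina4-ps1 fell to log2 values between 4.10 and 4.22, the organic anion transporter Slco1a1 to between 2.73 and 2.98, and carbonic anhydrase 3 (Car3) fell by 7.13. The other large falls were Mup21, Slc22a30, Pon1, Mup3, Hsd3b5, Cyp2c50, Rgn, Akr1c6, Cyp2c54, Elovl3 and Ugt3a2, the last at −5.31. In 5 of the 15 rises (Slc7a11, Apela, Casp12, Cpe and Slc34a2) and 5 of the 15 falls (Sult2a8, Serpina4-ps1, Slco1a1, Hsd3b5 and Elovl3), the dimmer group's mean lay under the lower quartile of its arrays (means of 4.34 and 4.31). Such values were not shown to be above background, so the sizes of these changes may be understated and their ranks carry no order. With the dimmer group set to that quartile, Slc7a11 differed by 6.09, Sult2a8 by 7.35 and Slco1a1 by 5.73 in size. Values of the Mup, Cyp2c, Ugt and Sult2a genes are uncertain, since near-identical family members can hybridise to the same probes.

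Of 19938 genes tested, 2106 changed at a limma adjusted p under 0.05, 1117 risen and 989 fallen. At least 2-fold changes numbered 747 up and 562 down, and changes of 16-fold or more 23 up and 36 down. Risen genes made up 53% of the calls, and 42.7% of the calls when each array was shifted to a common median. The tumour and control values did not overlap for 44.2% of genes, where chance gives 20%. An exact permutation test of 2 arrays against 3 cannot go below p = 0.1 (two-sided), so single-gene calls rest on the spread that limma shares across genes. The count was 129 without control 1, 108 without control 2 and 1266 without tumour 2. A test per gene with no shared spread called 18. Among the 15 largest rises, Igfbp1, Ly6d, Apela, Cpe, Slc34a2 and Gipc2 lost their call without either control, and Cpe without tumour 2. Among the 15 largest falls, 7 kept it without either control (Sult2a8, Serpina4-ps1, Slco1a1, Car3, Mup21, Hsd3b5 and Elovl3), and Slc22a30, Pon1, Cyp2c50, Rgn, Akr1c6 and Cyp2c54 also lost it without tumour 2.

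**Figure D1:**
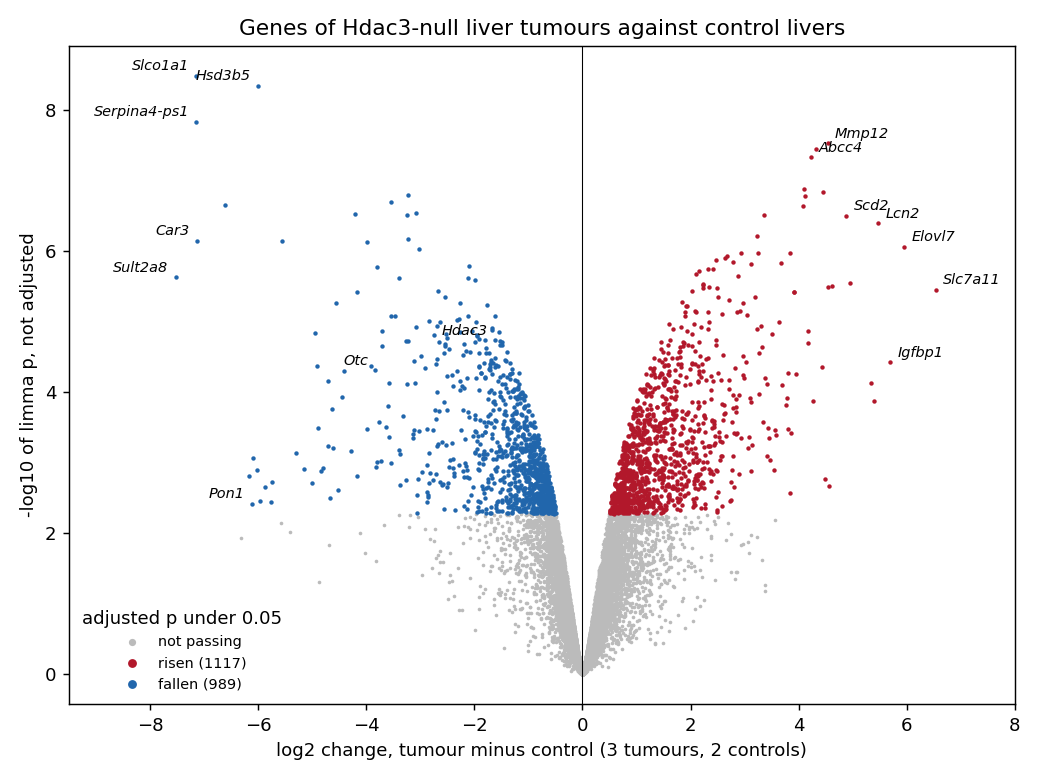
Each point is a gene, with its log2 change (tumour minus control) on the horizontal axis and −log10 of the limma p before adjustment on the vertical axis. Red points are the 1117 risen genes and blue points the 989 fallen genes. Slc7a11 lies farthest to the right (6.53) and Sult2a8 farthest to the left (−7.53).

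Many genes normally higher in male than in female liver fell. Of 21 measured male-biased genes, 10 fell and 0 rose (19 fell with adjustment over the list alone), with a median log2 change of −2.63. Besides Slco1a1, Mup21 and Elovl3, the steroid dehydrogenase Hsd3b5 fell by 6.01, to log2 values between 4.11 and 4.25 in the tumours. The list was shifted down by limma's camera test (adjusted p = 2.4e-14; adjusted p = 0.192 with an estimated correlation). The 4 members with the smallest p kept their calls with any of the arrays left out. The macrophage marker list shifted up by a median of 2.10 in the same tumours.

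Some genes of nitrogen disposal, drug metabolism and bile acids fell as well, and in each of these lists most members did not pass the test. In the list of the urea cycle and amino acid breakdown, 7 of 19 members fell and 0 rose (14 fell with adjustment over the list alone). Otc, which makes citrulline in the urea cycle, fell by 3.83, Prodh2 by 3.11, Prodh by 2.74, and Nags by 0.97 (list adjusted p = 5.78e-09; adjusted p = 0.383 with an estimated correlation). Of 24 cytochrome P450 and phase II genes, 8 fell and 0 rose (13 when adjusted over the list alone), including Ugt3a2, Ces3a (−4.96), Cyp1a2 (−1.62) and Sult5a1 (−1.13). This list was shifted down (adjusted p = 4.69e-07; adjusted p = 0.383 with an estimated correlation). Of 23 genes of bile acid synthesis and transport, which were tested as 1 list, 7 fell and 2 rose (16 and 3 when adjusted over the list alone). Cyp7b1 fell by 3.47 and Hsd3b7 by 1.70, both enzymes of bile acid synthesis, while the export pump Abcc4 rose by 4.23 (list adjusted p = 5.37e-05; adjusted p = 0.52 with an estimated correlation). Without control 1 or control 2, the named calls of the urea cycle and P450 lists were lost (highest adjusted p 0.149 and 0.164, 0.159 and 0.165), and of the named bile acid genes only Hsd3b7 was lost (0.0699 and 0.073). Markers of macrophages moved the other way in these tumours, by a median of 2.10. Fry called the P450 and bile acid lists (adjusted p = 0.0489 and 0.0448) but not the urea cycle list (0.0532).

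Genes of sterol synthesis fell in 13 of 20 measured cases, with 0 risen (15 fallen when adjusted over the list alone). Ebp fell by 2.47, Tm7sf2 by 2.31, Nsdhl by 1.65 and Stard4, a sterol carrier, by 1.07. The list's median was −1.01 and it was shifted down (adjusted p = 1.91e-08; adjusted p = 0.383 with an estimated correlation). In sugar metabolism, Hk2 rose by 2.78, Pfkp by 3.68 and Pkm by 2.41, isoforms that adult hepatocytes normally express little, while Aldoc fell by 1.80. Of 17 glycolysis genes, 4 rose and 2 fell (5 and 2 when adjusted over the list alone), and the list was shifted up (adjusted p = 0.002; adjusted p = 0.383 with an estimated correlation). Of 19 genes of gluconeogenesis and glycogen, 3 fell and 3 rose (7 and 3 when adjusted over the list alone). Gys2, the liver glycogen synthase, fell by 1.92 and Ppp1r3c by 1.74, and Ugp2 rose by 0.83. This list was shifted down (adjusted p = 0.0383; adjusted p = 0.521 with an estimated correlation), a call lost with dim genes left out and with arrays shifted to a common median (adjusted p = 0.0953 and 0.134). Of 37 respiratory chain subunits, 4 fell and 0 rose (4 when adjusted over the list alone): Sdha by 0.90, Uqcrb by 0.88, Ndufb5 by 0.76 and Ndufb8 by 0.75. The median was −0.36 (list adjusted p = 1.22e-07; adjusted p = 0.521 with an estimated correlation). Without either control, Tm7sf2, Hk2 and Pfkp kept their calls and the other genes named in this paragraph lost them, the highest adjusted p being 0.231 without control 1 and 0.228 without control 2. Ppp1r3c and Uqcrb were also lost without tumour 2, and Ndufb5 without tumour 1. The macrophage list moved by a median of 2.10 beside these groups. Fry called the sterol and glycolysis lists (adjusted p = 0.0285 for each). It did not call gluconeogenesis and glycogen (0.187) or the respiratory chain (0.0925).

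Genes of the perivenous zone of the lobule and targets of beta-catenin were tested as 1 list, which does not separate them. Of its 24 measured members, 11 fell, 0 rose and 13 did not pass (16 fell when adjusted over the list alone), with a median of −1.23. Lgr5 fell by 1.70 and Axin2 by 0.82, both targets of beta-catenin, and Cyp1a2 by 1.62 (list adjusted p = 4.05e-08; adjusted p = 0.383 with an estimated correlation). Adgrg2 was also called fallen, but both of its group means lay under the lower quartile of the arrays, so it carries no weight here. Of 20 periportal genes, 3 rose and 2 fell (3 and 6 when adjusted over the list alone), and the list was not shifted (adjusted p = 0.242). Cdh1, which encodes E-cadherin, rose by 2.93, Ctsc by 2.17 and Hsd17b13 by 0.98, and Hal, the histidine ammonia-lyase, fell by 2.39. Whether the zones differed from each other was not tested. Clock genes and targets of the REV-ERB nuclear receptors, which recruit Hdac3, were tested as 1 list, which does not separate them. Of its 21 measured members, 9 fell and 1 rose (11 and 3 when adjusted over the list alone). Dbp fell by 1.88, Ciart by 1.83, Tef by 1.54 and Per3 by 1.49 (list adjusted p = 0.000132; adjusted p = 0.383 with an estimated correlation). The time of day of tissue collection is not given in the sources used here. Of the genes named in this paragraph, Cdh1 kept its call without either control and the others lost theirs (highest adjusted p 0.184 and 0.212), as did Axin2 and Hal without tumour 2 (highest adjusted p 0.0556 and 0.0525). Macrophage markers shifted up by a median of 2.10 beside these lists. Fry called the clock list (adjusted p = 0.036) but not the perivenous and beta-catenin list (0.0503).

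Transcription factors and secreted proteins that define hepatocytes fell in part. Of 23 secreted proteins and identity factors, 6 fell and 0 rose (6 when adjusted over the list alone), with a median of −0.28. The transcription factor genes Nr1h4 (−1.38), Foxa2 (−0.98) and Prox1 (−0.74) fell, as did coagulation factor F9 (−1.30), while Alb stood at −0.12 (adjusted p = 0.744). The list was shifted down (adjusted p = 0.000985; adjusted p = 0.521 with an estimated correlation). Markers of fetal liver and liver cancer rose in 9 of 35 cases, with 0 fallen (11 when adjusted over the list alone): Scd2 by 4.88, Ly6d by 5.39, Cbr3 by 4.28 and Golm1 by 2.78. Their median was 1.07, with 0.98, 0.29 and 1.15 in tumours 1, 2 and 3 (list adjusted p = 7.6e-07; adjusted p = 0.21 with an estimated correlation). Afp, the fetal counterpart of albumin, rose by 1.13 (adjusted p = 0.00997), a call lost without control 1 (0.105) or control 2 (0.127). Without either control Scd2 kept its call, and the other identity and cancer marker genes named for their small p lost theirs, the highest adjusted p being 0.235 without control 1 and 0.251 without control 2. Prox1 was also lost without tumour 1 or tumour 2, Nr1h4 without tumour 1 and F9 without tumour 2. The median shift of macrophage markers in these tumours was 2.10. Fry called the list of fetal and cancer markers (adjusted p = 0.0197) but not the hepatocyte list (0.0666).

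Many genes of cell division were higher in the tumours, though in the mitosis and replication lists most members did not pass the test singly. Of 44 genes of mitosis, 19 rose and 0 fell (31 when adjusted over the list alone), and all 44 lay above the control mean. Ect2 rose by 2.63, Tpx2 by 2.08 and Prc1 by 1.63, and Cdk1, the mitotic kinase, rose 2.82-fold. The control means of Tpx2 and Prc1 lay under the lower quartile of the arrays (4.07 and 4.34), so the sizes of their rises are uncertain. The median was 1.21, and the per-tumour medians were 0.65, 1.29 and 1.48 (camera adjusted p = 1.37e-15, or 0.425 with an estimated correlation). Fry did not call this list (adjusted p = 0.0712), and its members had an estimated correlation of 0.61 against the preset 0.01. Of 40 genes of DNA replication and the entry into S phase, 8 rose and 2 fell (16 and 2 when adjusted over the list alone). Mcm6 rose by 2.60, cyclin D1 (Ccnd1) by 2.34 and Mcm3 by 1.82, whereas Mcm10 fell by 1.98 (list adjusted p = 4.98e-06; adjusted p = 0.582 with an estimated correlation). Of 29 genes of ribosomal proteins and ribosome assembly, 2 rose, Nop58 by 1.60 and Rps19 by 0.74, and 0 fell (5 risen when adjusted over the list alone). Rpl5 (0.50) and Nip7 (0.77) did not pass, and the list was shifted up (camera adjusted p = 5.51e-05, or 0.582 with an estimated correlation). Fry called neither the ribosome list nor the replication list (adjusted p = 0.187 and 0.215). Of these named genes, Mcm10 kept its call without control 1, the others were lost without either control (highest adjusted p 0.263 and 0.258), and Tpx2, Nop58 and Rps19 were lost without tumour 2, and Rps19 without tumour 1. In the same tumours the macrophage list shifted up by a median of 2.10 and the cholangiocyte list stood at per-tumour medians of 1.08, 0.84 and 0.94.

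The study's title concerns chromatin structure and genome stability, and genes of both were examined. Of 39 genes of double-strand break repair and damage checkpoints, 0 passed the test, also when adjusted over the list alone. Fancc (−0.67), Mdc1 (0.53), Trp53bp1 (0.65) and Chek2 (0.86) had adjusted p between 0.0511 and 0.0682. The list's median was 0.29 and it was shifted up (adjusted p = 0.009; adjusted p = 0.727 with an estimated correlation), a call lost with dim genes left out (adjusted p = 0.38). In the other repair pathways Msh3, a mismatch repair gene, fell by 1.15, Pms1 fell by 0.93 and Ddb1, a sensor of damaged nucleotides, rose from 10.07 and 10.15 in the controls to 10.79, 11.23 and 11.30, while Neil3 (0.85, with a control mean under the lower quartile) and the rest of 28 did not pass (1 risen and 2 fallen also when adjusted over the list alone). That list was not shifted (adjusted p = 0.943), and its median (0.01) and mean (−0.02) differed in sign. Of 25 targets of p53, 5 rose and 1 fell (8 and 2 when adjusted over the list alone): Btg2 rose by 3.63, Tnfrsf10b by 1.59, Ddit4l by 1.58 and Apaf1 by 1.32 (list adjusted p = 0.0019; adjusted p = 0.582 with an estimated correlation). The medians in tumours 1, 2 and 3 were 0.20, 0.47 and 1.09 for the p53 targets and 0.05, 0.25 and 0.52 for double-strand break repair. The macrophage list median was 2.10. Fry called neither the p53 list nor the double-strand break list (adjusted p = 0.117 and 0.429).

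Of 13 measured core and linker histone genes, 0 passed, also when adjusted over the list alone (list adjusted p = 0.491). H1f5 stood at 1.88, H2bc4 at −0.79, H1f1 at 0.59 and H4c8 at −0.23. Of 25 other deacetylases and subunits of their complexes, 5 fell and 1 rose (6 and 3 when adjusted over the list alone). Sirt3 fell by 1.27, Hdac11 by 0.85 and Hdac6 by 0.77, and Sirt6 rose by 0.70. The histone chaperone genes Chaf1b and Nap1l1 rose by 1.03 and 0.93, and Chaf1a (0.77) and the acetyltransferase Kat2b (−0.74) did not pass; of 20 acetyltransferases and chaperones, 2 rose and 0 fell (3 and 1 when adjusted over the list alone). Neither list was shifted (adjusted p = 0.943 and 0.754), and in both the median and the mean differed in sign (0.11 and −0.02, −0.01 and 0.11). Of the genes named for repair, p53 and chromatin, Btg2 kept its call without either control and the others lost theirs (highest adjusted p 0.264 and 0.299), and Pms1, Ddb1, Hdac6, Sirt6, Chaf1b and Nap1l1 were also lost without tumour 2. Without tumour 1, Pms1, Hdac6, Sirt6 and Sirt3 were lost.

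Antioxidant genes rose as a group. Of 25 genes of the NRF2 pathway and glutathione metabolism, 14 rose and 0 fell (16 and 2 when adjusted over the list alone), with a median of 1.30. Abcc4 rose by 4.23, the quinone reductase Nqo1 by 3.12, Srxn1 by 2.87 and Pgd, of the pentose phosphate pathway, by 2.22. The list was shifted up (adjusted p = 6.94e-13; adjusted p = 0.21 with an estimated correlation), and these 4 genes kept their calls with any of the arrays left out. The macrophage list shifted up by a median of 2.10 in the same tumours.

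Some inflammatory genes were also higher, and in each of the lists tested for them most members did not pass the test. Of 30 NF-kB targets and chemokines, 9 rose and 0 fell (13 when adjusted over the list alone): Lcn2 by 5.47, Cxcl16 by 2.33, the adhesion molecule Icam1 by 1.84 and Cx3cl1 by 1.07 (list adjusted p = 3.46e-07; adjusted p = 0.383 with an estimated correlation). Of 24 interferon response genes, 6 rose and 0 fell (13 when adjusted over the list alone). Usp18 rose by 1.96, Oasl2 by 1.60, Irf7 by 1.07 and Oasl1 by 1.02 (list adjusted p = 2.65e-07; adjusted p = 0.383 with an estimated correlation). Acute-phase genes went both ways, with 5 risen and 3 fallen of 26 (6 and 4 when adjusted over the list alone). The metallothionein genes Mt2 and Mt1 rose by 3.86 and 2.52 and the pentraxin Apcs by 1.81, while Saa4 fell by 5.01 and Crp by 3.05. That list was shifted up (adjusted p = 0.0491; adjusted p = 0.727 with an estimated correlation), a call lost with dim genes left out (adjusted p = 0.137). The macrophage list, whose cells express many of these genes, shifted up by 2.10 in the same samples. Fry called the NF-kB list (adjusted p = 0.0481) but neither the interferon list (0.0503) nor the acute-phase list (0.224). Of the named members with the smallest p, Lcn2 and Cxcl16 kept their calls without either control, Usp18 without control 1, and the others were lost (highest adjusted p 0.138 and 0.24), as were Saa4 (0.186 and 0.231) and Crp (0.193 and 0.212); Irf7 was also lost without tumour 1 (0.0538) and Saa4 without tumour 2 (0.0826).

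Many macrophage markers rose in the tumours. Of 35 markers of Kupffer cells and macrophages, 22 rose and 1 fell (25 and 1 when adjusted over the list alone), with a median of 2.10 and per-tumour medians of 2.24, 1.79 and 2.45. Mmp12, a macrophage elastase, rose by 4.54, the complement gene C1qc by 3.33, Cd9 by 3.26 and Lgals3 by 2.64, and Cd163, a scavenger receptor of resident macrophages, fell by 2.20, a call lost without either control (0.0581 and 0.0847). The list was shifted up (camera adjusted p = 6.98e-15, or 0.383 with an estimated correlation). Whether other cells of the tumours express some of these markers was not tested, so the median is no direct measure of macrophage number. Of 24 B and plasma cell markers, the 4 that rose were Cd74 (3.41) and the class II genes H2-Eb1 (3.69), H2-Aa (3.80) and H2-Ab1 (4.18), which macrophages and dendritic cells also express. With adjustment over the list alone, 6 rose. The list was called shifted up (adjusted p = 0.0119; adjusted p = 0.521 with an estimated correlation), but its median was 0.10, the per-tumour medians were 0.24, 0.13 and 0.04, and 15 of 24 lay above the control mean. Control 1 minus control 2 had a larger median, 0.25. Among 25 T and NK cell markers, 0 passed, also when adjusted over the list alone. Ccl5 (2.38), Cd3g (2.22), Cd8a (1.27) and Cd8b1 (0.75) were highest in tumour 3, Cd3g with a control mean under the lower quartile of the arrays, and the list was shifted up (adjusted p = 0.0067; adjusted p = 0.725 with an estimated correlation), a call lost with dim genes left out (adjusted p = 0.103). Of 19 neutrophil markers 0 passed, also when adjusted over the list alone, with Csf3r at 0.58 and Il1f9, whose control mean lay under the lower quartile, at 2.82 (list adjusted p = 0.347). Cxcr2 and Ly6g lay under it in both groups. Fry called the macrophage list (adjusted p = 0.0197) but neither the B cell list (0.0666) nor the T and NK cell list (0.436).

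Of 32 stellate cell and matrix genes, 7 rose and 0 fell (10 when adjusted over the list alone): Vim by 1.92, the basement membrane collagens Col4a1 by 1.68 and Col4a2 by 1.59, and Timp2 by 1.14. The per-tumour medians of this list were 1.09, 0.54 and 0.10 (camera adjusted p = 5.51e-05, or 0.582 with an estimated correlation). Fry did not call this list (adjusted p = 0.144). Of 19 cholangiocyte and progenitor markers, 5 rose and 1 fell (8 and 1 when adjusted over the list alone). Bicc1 rose by 3.08, Anxa3 by 2.40 and St14 by 2.25, and Onecut1, a transcription factor that hepatocytes also express, fell by 2.91 (list adjusted p = 9.56e-05; adjusted p = 0.21 with an estimated correlation). Of 31 endothelial markers, Cd34 rose by 2.25, Flt4 by 2.22, Emcn by 2.11 and Plvap by 1.58, and 27 did not pass (5 risen when adjusted over the list alone). The endothelial list was not shifted (adjusted p = 0.242), with per-tumour medians of 0.67, 0.16 and −0.26. Of 16 erythroid and blood markers Tfrc, the transferrin receptor, rose by 1.60, and Alas2 (−3.20), Klf1 (−0.88) and Pf4 (0.61) did not pass (list adjusted p = 0.954; 1 risen and 2 fallen when adjusted over the list alone). Of 14 adipocyte and pancreas markers, Fabp4 rose by 4.55, and Pnliprp1, under the lower quartile in both groups, Retn and Cpa1 did not pass. The list was not shifted (adjusted p = 0.943), its median (−0.07) and mean (0.27) differed in sign, and Fabp4 alone was called when adjusted over the list alone. Of the cell type genes named by the rule, Mmp12, Lgals3 and Fabp4 kept their calls without either control, C1qc without control 2 and H2-Ab1 without control 1, and the others were lost (highest adjusted p 0.263 and 0.224). Cd34, Flt4 and Plvap were also lost without tumour 2, and Emcn and Plvap without tumour 1.

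**Figure D2:**
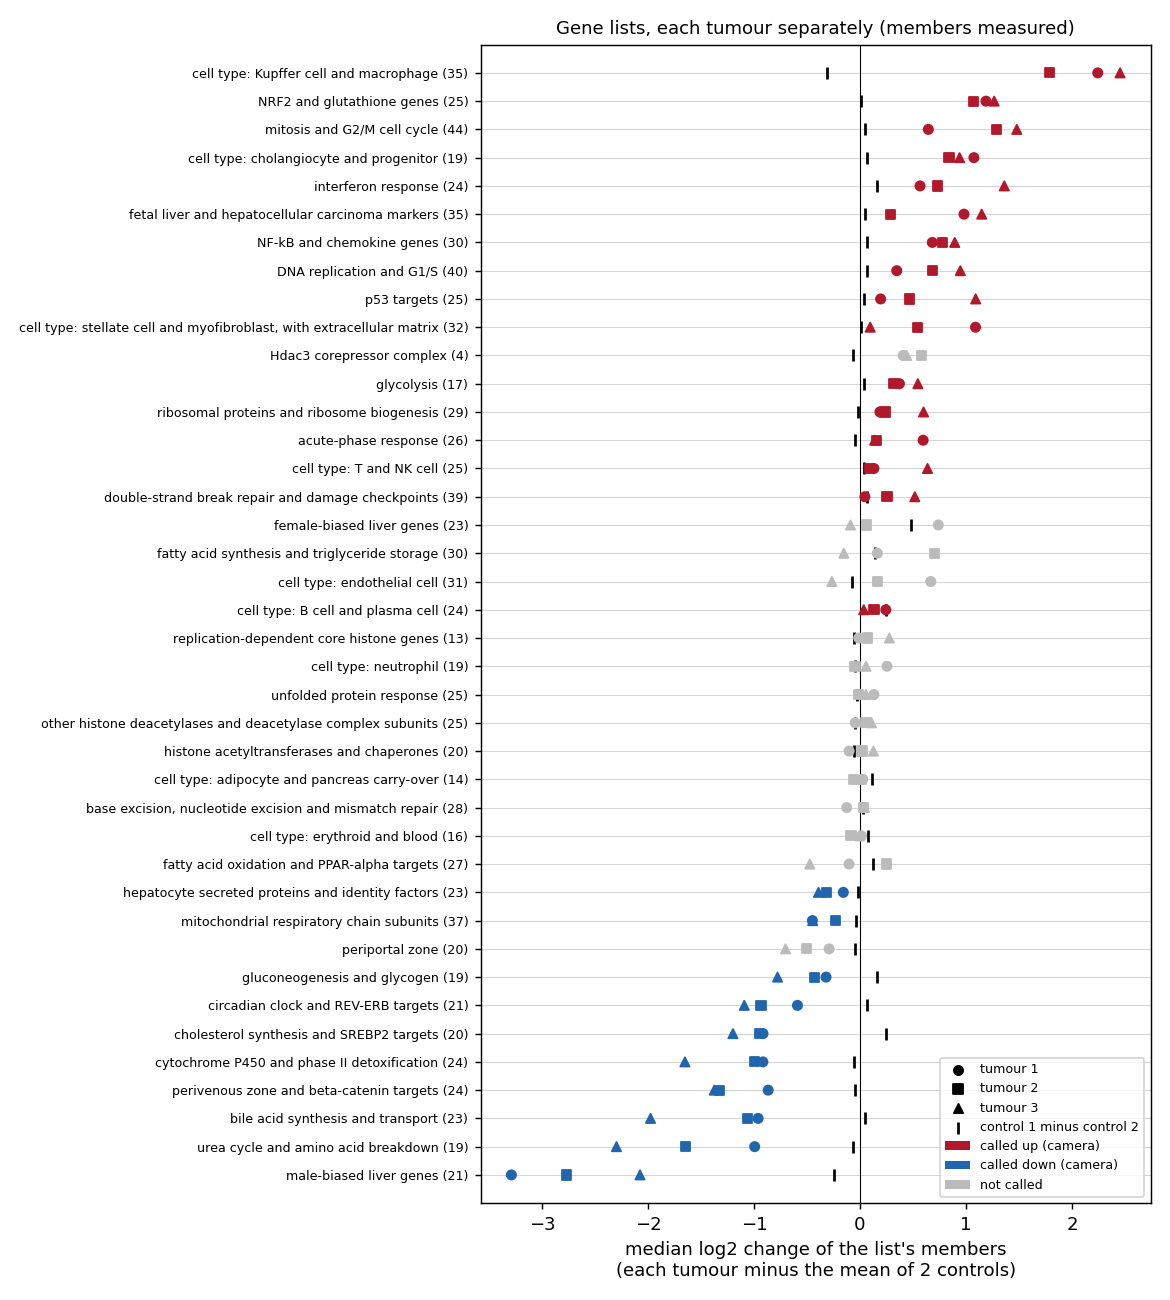
Each line is a gene list with its number of measured members, and the red, blue or grey symbols give the median log2 change of its members in tumours 1, 2 and 3, each against the mean of the 2 controls; the black tick is control 1 minus control 2. By the mean of the per-tumour medians, the macrophage list lies farthest to the right (1.79 to 2.45) and the male-biased list farthest to the left (−3.29 to −2.08). In tumour 3 alone, the list of the urea cycle and amino acid breakdown lies farther left (−2.30).

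The spread within the groups was described without a test. Across genes, the Pearson correlation was 0.992 between the controls, 0.983 between tumours 1 and 2, 0.971 between tumours 2 and 3 and 0.964 between tumours 1 and 3; genes are not independent replicates. The median SD of a gene was 0.10 in the controls and 0.175 in the tumours, and 24 and 350 genes had an SD over 1 log2 unit. Cyp2e1, the ethanol-inducible P450, had the largest range among tumours, with log2 values of 11.49, 8.87 and 4.10 against 13.06 and 12.98 in the controls. Hamp, the iron hormone hepcidin, stood at 10.03, 4.13 and 4.37 against 12.48 and 12.50. Slco1b2 stood at 9.23, 6.49 and 3.77 and Hsd17b6 at 9.55, 4.47 and 6.09, both above 11 in the controls. Tspan8 (10.07, 6.47 and 4.49), Akr1c18 (9.63, 5.91 and 4.41) and Cyp17a1 (10.12, 4.70 and 4.38) were highest in tumour 1, as were Vsig4 (9.84, 7.34 and 4.55), a marker of resident Kupffer cells, and Cyp2c38 (8.32, 6.68 and 2.99). Krt23 was highest in tumour 3 (5.06, 4.26 and 9.60). None of these 10 genes passed the limma test between groups, with adjusted p from 0.0711 for Slco1b2 to 0.957 for Vsig4.

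**Figure D3:**
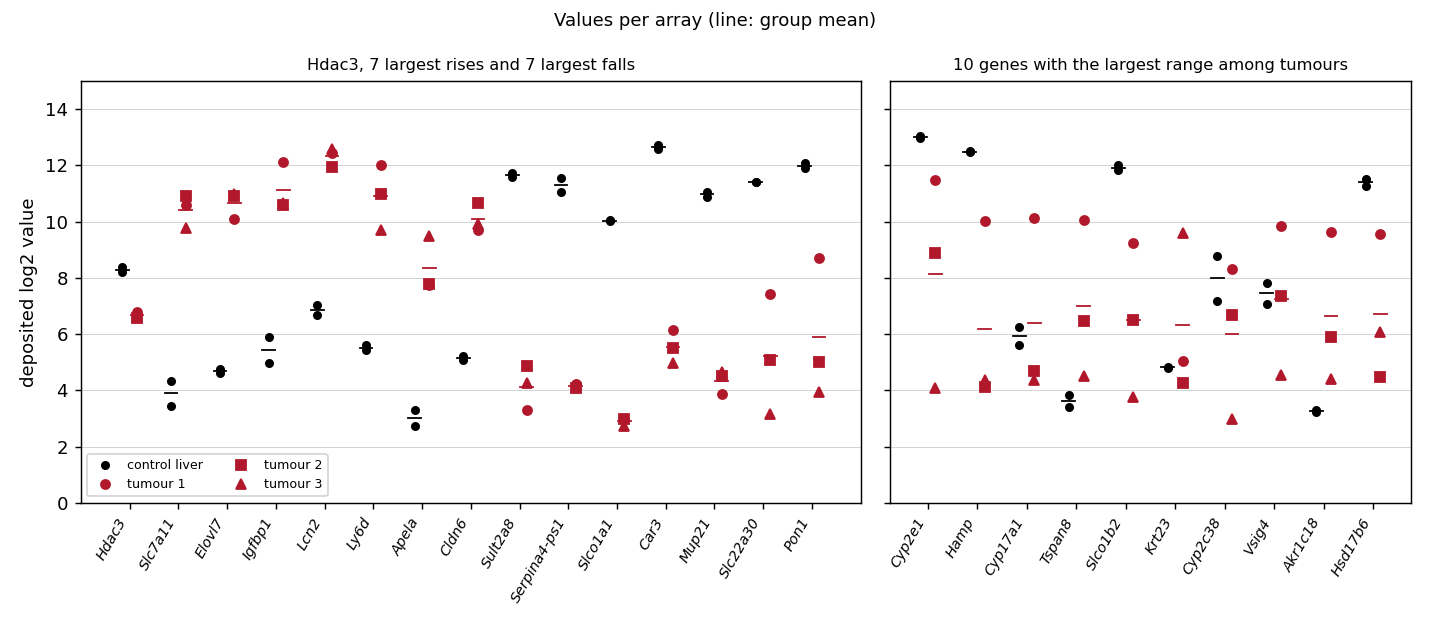
Deposited log2 values per array for Hdac3, the 7 largest rises and the 7 largest falls (left) and for the 10 genes with the largest range among tumours (right); black circles are the 2 control livers, red symbols the 3 tumours, and short lines the group means. Hdac3 lies between 6.57 and 6.78 in the tumours, and Cyp2e1 spreads from 4.10 to 11.49.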

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

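The test of probe sets without a single gene symbol was planned. Outside the named genes, 191 of the 7064 probe sets with several symbols or none rose in the tumours and 155 fell, when all 28853 probe sets were tested together with limma. The changed share was 4.90% among them and 9.71% among probe sets with 1 symbol, and the highest rise was 4.07 log2 units. They are listed because they are signals outside the main comparison, and their genes were not analysed here.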

How the results depend on the processing

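All alternatives named here were planned before the data were examined. All 2106 called genes kept their sign with another scaling, the mean of all probe sets, array weights, a replicate block or a left-out array. With a variance trend, an ordinary test or dim genes left out (1931 still tested), the log2 changes are the same, so no sign could turn. The genes were selected in these same arrays for differences large against their spread, so kept signs say little about how firm the calls are. The count of changed genes was 3252 with array weights (tumour 3 had the lowest weight, 0.413), 18 with an ordinary test per gene (13 at least 2-fold; Hdac3 −1.62, adjusted p = 0.0704), 505 at adjusted p under 0.01 and 3326 under 0.1. With arrays left out in turn, it ranged from 108 (without control 2) to 2719 (without tumour 3), with 129 without control 1, 1266 without tumour 2 and 2021 without tumour 1. The at least 2-fold count ranged from 108 to 1502, and the Hdac3 change from −1.71 to −1.54, its adjusted p over all alternatives from 0.000914 to 0.0704. With 1 control left, the spread was taken from the tumours alone, whose median gene SD was 0.175 against 0.10 in the controls. Calls lost there need not rest on the values of the control left out. Fewer controls also leave less information on the control mean. Causes of the other changes were not tested. Called lists numbered 0 with an estimated correlation, 11 by fry and 25 to 27 with arrays left out. Of 141 named genes called, 31 kept the call without control 1, 29 without control 2, 127, 110 and 140 without tumours 1, 2 and 3, and 136 to 141 under the other settings, except 5 with the ordinary test and 138 of 138 tested with dim genes left out. Risen calls were 42.7% with arrays shifted to a common median (53% before), and the median of all genes then lay at −0.12 instead of −0.02. Signs turned only for genes not called: Gps2 to −0.0398 with that shift, and Vsig4 to 0.28 with array weights. With arrays left out, Vsig4 ranged from −1.50 to 1.14, Krt23 from −0.15 to 2.52 and Cyp17a1 from −1.39 to 1.48, the last with adjusted p = 0.0357 without tumour 1.

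The replicate numbers did not pair the samples: deviations from the group means correlated at 0.0039 for number 1 and −0.0129 for number 2. With the replicate block, 2376 genes and 28 lists were called, Hdac3 changed by −1.62, Vsig4 turned to 1.14 and Krt23 to −0.15. Tumour 3 has no partner there and drops out of the estimate. Arrays give no depth, and dim genes near the background limit what can be seen: 36 of 40 lists kept their side of the threshold with dim genes left out.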

Other observations

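The tests of the 3 patterns weighed here were all chosen after the results were seen, while the gene lists were fixed beforehand. In lipid handling, Scd2 and Fabp4 rose by 4.88 and 4.55, and the lipid droplet genes Cidec and Plin2 by 3.07 and 1.34. Of 30 genes of fatty acid synthesis and storage, 5 rose and 4 fell (5 and 4 also when adjusted over the list alone), and the list was not shifted (adjusted p = 0.242). Of 27 genes of fatty acid oxidation and PPAR-alpha targets, 2 rose and 2 fell (3 and 3 when adjusted over the list alone; list adjusted p = 0.656): Acot2 by 2.73 and Vnn1 by 2.48 rose, and Acaa2 fell by 1.23 and Fabp1 fell 2.82-fold. Without either control Scd2 and Fabp4 kept their calls and the others lost theirs, the highest adjusted p being 0.231 and 0.28. Fabp1 was also lost without tumour 1 (0.0668), Acot2 and Vnn1 without tumour 2 (highest 0.12) and Vnn1 without tumour 3 (0.057).

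Of 23 genes normally higher in female liver, Cd36, a fatty acid transporter, rose by 1.89 and 0 fell (0 called when adjusted over the list alone), and the list was not shifted (adjusted p = 0.7). Vldlr (−0.89), Atp6v0d2 (0.98) and Hao2, under the lower quartile of the arrays in both groups, did not pass. Control 1 exceeded control 2 by a median of 0.48 in this list, and Cd36 lost its call without control 1, control 2, tumour 1 or tumour 2 (adjusted p 0.0521, 0.157, 0.0592 and 0.094). In the unfolded protein response, Atf3 rose by 3.10, Trib3 by 2.79 and Atf6 by 0.60, and Herpud1 fell by 1.57. Of its 25 genes, 3 rose and 2 fell (4 and 2 when adjusted over the list alone), and the list was not shifted (adjusted p = 0.353). All 4 named genes lost their calls without control 1 or control 2 (highest adjusted p 0.238 and 0.258), Trib3, Atf6 and Herpud1 without tumour 2, and Atf6 without tumour 1.

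Runs of neighbouring genes, in GRCm38.p6 order, shifted together in the tumours: the lowest median over 51 neighbours was −0.79 in tumour 2, more extreme than in each of 1000 shuffles of gene order (permutation p = 0.001, the smallest these can give), while 0 windows passed in control 1 minus control 2. Some runs had like medians in more than 1 tumour. Apcs to Smyd3, found in tumour 1, stood at 0.79, 0.73 and 0.72 in tumours 1, 2 and 3. In tumours 2 and 3, 1700123O20Rik to R3hcc1, found in tumour 2, stood at −0.47 and −0.45. Of runs found in tumour 3, Nid1 to Mcur1 stood at −0.47 and −0.65 in tumours 2 and 3, and Nedd8 to Cab39l at −0.55 and −0.58. Runs were found in each tumour on its own, so those of different tumours may overlap and are not separate regions. The longest, 201 genes from Cmah to Msh3, was found in tumour 2 and had medians of −0.10, −0.60 and −0.32 in tumours 1, 2 and 3; to avoid reading it on genes selected for it, the lowest window was found with every other gene and read on the 24 genes left out, all inside that run. Their medians were −0.16, −0.64 and −0.19 in tumours 1, 2 and 3 (bootstrap interval over genes −0.90 to −0.41 in tumour 2). They lay −0.62 from the mean of the other tumours (−0.73 to −0.32). Tumour 2 was picked for its run, and the intervals treat neighbouring genes as independent. They do not measure the spread between tumours, so an equal shift in the 3 tumours is not excluded. A segment present in fewer copies in tumour 2 may account for this part, but copy number was not measured here. Regional control of transcription, a shared programme of unequal strength and strain segments were not tested and stay open, as does the cause of the runs seen in more than 1 tumour.

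Some hepatocyte genes fell while many macrophage markers rose, which a lower share of hepatocytes might give. As the only change, a lower share would raise the markers of every other cell type alike. The macrophage median exceeded the endothelial one by at least 1.58 in every tumour. Both medians were known when this comparison was chosen. The endothelial list held 4 risen members beside 27 that did not pass, so its median need not stand for all other cell types. Admixed cells also lower every hepatocyte transcript by 1 factor, yet at a matched control level the male-biased genes lay below the hepatocyte list by at least 1.25. A lower share of hepatocytes as the only change therefore does not account for the whole pattern, although part of the shift may still come from cell composition. More macrophages beside a hepatocyte programme that is itself changed stay open, and tumour tissue and loss of Hdac3 were not separated by the design.

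Tumour 1 kept part of the control level of Cyp2e1, Hamp, Slco1b2 and Hsd17b6, between 15.5% and 34.5%, and the other tumours stood lower. Control-like hepatocytes left in that sample could give this, but they would bring their other abundant transcripts too. Of 17 male-biased genes with a control log2 value over 9, 5 stood in tumour 1 at 1.80% of the control level or less (Slco1a1, Mup21, Mup3, Hsd3b5 and Elovl3), and the median of the 17 was 8.93%; 8 stood between 26.2% and 107%, which expression by the tumour cells themselves could add. This test replaced a first version on the fallen members only, with the same outcome. Hepatocytes that lack Hdac3 but are not tumour cells, and differences between tumours, were not tested and stay open.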
